A study of Mus musculus with 6 samples.

How the data were processed

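Messenger RNA was sequenced from the forebrains of 6 mice at postnatal day 9. The conditional knockout group (cKO) held 3 Parp1 floxed mice that carried Pdgfra-CreER, a tamoxifen-inducible recombinase driven by the Pdgfra gene, which marks oligodendrocyte precursor cells. The control group held 3 floxed littermates without the recombinase. All 6 mice received tamoxifen by intraperitoneal injection once a day from postnatal day 1 to 3, per the labels. RNA was selected by poly-T beads and made into libraries with a directional kit, per the labels' protocols.

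The deposited counts are whole numbers of reads per Ensembl gene. CASAVA, STAR 2.5, HTSeq 0.6.1, DESeq and the mouse build mm10 are named in the submitters' processing notes, without their roles. The strand setting of the counting and the annotation release are not given in the sources used here. A wrong or absent strand setting would mix reads of overlapping genes on opposite strands, so the counts of genes with such overlaps are less certain. Of the genes printed that the naming rule took, Gpr17, Lims2, Bcas1, Sirt2, Tnr, Pdgfra, Sox8, Sox4, Csf1r, Parp9, Cgas and Myef2 have exons that overlap a gene on the opposite strand. Genes named outside the rule were not checked for overlaps. The deposited FPKM values (fragments per kilobase of gene, scaled to the library total) equalled the deposited count divided by 1 fixed length per gene and by the table's total. In 100% of the values this length came out whole within 0.01 bp, so the FPKM values are the same measurement as the counts on another scale. The table held 35275 gene identifiers, of which 34490 had a name in the GENCODE M21 annotation and 785 did not. The unnamed identifiers took 0.119% to 0.130% of a library's counts. Coordinates are those of that annotation, on the same build, mm10.

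Total counts per library ran from 17262042 to 29310193. Tests were run on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes with too few reads were removed by filterByExpr with the group (a minimum count of 10 and a minimum total of 15), which left 16938 genes. Library sizes were scaled by TMM, and cKO was compared with control by edgeR's quasi-likelihood test with robust dispersion, as a two-sided test of 3 mice against 3. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels are in TMM-normalised CPM, counts scaled to the library total, as mean ± SD over n = 3 mice per group. The log2 fold changes are those of cKO against control. Confidence intervals are at 95%.

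Gene lists were tested by camera in limma 3.58.1, on log2 CPM with voom weights and a preset correlation of 0.01 between genes. Camera compares the genes of a list with all other tested genes. The 29 lists with at least 4 tested genes were adjusted together. Camera with a correlation estimated from the data and fry were run beside it. Fry asks another question, whether the genes of a list shift in a shared direction between the groups, without comparing them with other genes. The lists covered 4 stages or regulators of the oligodendrocyte lineage (precursor, newly formed and premyelinating, myelin and mature, and lineage transcription factors), inhibitors of oligodendrocyte differentiation, and RNA-binding regulators. They covered lipid synthesis by a cholesterol and a sphingolipid list. Cell type lists were those of astrocytes, neurons, microglia, activated microglia, endothelium, pericytes, fibroblasts, choroid plexus and blood. Process lists were those of the cell cycle, p53 response, PARP family, base excision repair, NAD metabolism, immediate early genes, interferon response and integrated stress. Regional lists were those of the striatum, thalamus, hypothalamus and pituitary, olfactory bulb, and midbrain with hindbrain. X-inactivation and Y-linked genes were read per library only. Lists came from textbook markers and were not chosen on these samples.

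The samples' groups, the tests, the lists, the alternatives and the rule for naming genes were set before the data were examined, apart from those named as later choices. The rule named Parp1, and the 10 called genes with the largest rise and the 10 with the largest fall, among those with a mean of at least 1 CPM and groups that did not overlap. It also named the 4 members with the smallest p of each list that passed camera and of the oligodendrocyte and PARP lists. Mbp, Myrf, Pdgfra, Olig2, Sox10, Myef2 and Parp2 were named in any case. Some of the genes that the rule takes are not reported here. Other genes named were chosen after their values were seen.

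The alternatives were DESeq2 size factors, upper-quartile factors or library size in place of TMM, no filter or a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom with quality weights, and edgeR without robust dispersion. The deposited FPKM values were tested by limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5, and on log2(FPKM + 1) with no filter. Further alternatives left out each library in turn, took the replicate number as a block, took Xist as a covariate, left out the 594 genes on X and Y, or left out blood and choroid plexus genes. Thresholds of 0.1 and of a fold of at least 1.5 were also tried. A covariate for regional make-up was added after the data were seen.

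The edgeR script was tested on simulated counts made from the means of these libraries, with 16724 genes tested and 200 of them changed. It recovered 58.2% of the changed genes at 1.5-fold, 73.1% at 2-fold and 95.5% at 4-fold, and 7.19% of its calls were false. A further list was lowered as well, by a smaller fold, and calls of its genes were not counted as false. With no gene changed, edgeR called 2 of 16732 genes and camera called 0 lists. The simulated genes were drawn independently and the lists at random. The 0 lists therefore give no rate of false list calls where the genes of a list are correlated. Intervals on counts pooled over the mice of a group cover counting error only and leave out differences between mice. Reads carried no molecular identifiers, so even the counting error may be understated.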

Results

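The series measured gene expression in the forebrains of 6 mice at postnatal day 9, when oligodendrocytes of the mouse forebrain are starting to differentiate and myelinate. In 3 mice Parp1 had been floxed and deleted by tamoxifen in cells expressing Pdgfra (cKO), and 3 littermates with the floxed gene and no recombinase served as controls. Parp1 encodes the main enzyme that adds poly(ADP-ribose) chains to proteins. The comparison asked whether expression in the developing forebrain, above all of oligodendroglial and myelin genes, differed when Parp1 was deleted in this lineage. Total counts were 17262042, 21552334 and 22118915 in control replicates 1, 2 and 3, and 19934003, 24916865 and 29310193 in cKO replicates 1, 2 and 3. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom ran from 4.34 to 23.8, so each counted as 1 mouse.

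Some libraries stood apart for reasons other than genotype. Control replicate 3 separated from the other 5 libraries on the first principal component, which held 36.7% of the variance, at 43.5 against values from -16.2 to -3.62. Genes of the striatum averaged 2.52-fold lower there than in the other 5 libraries, and genes of the thalamus 1.93-fold higher. Ppp1r1b, the striatal phosphoprotein DARPP-32, was at 39.6 CPM in that library, and Slc17a6, a glutamate transporter of thalamic neurons, at 174 CPM. Control replicate 1 was the only library with Y-linked expression, with 1123 counts of Ddx3y and 3 of Xist. Each other library had at most 1 count of Ddx3y and at least 20196 of Xist. Sex is not labelled per mouse, and by these counts it was not balanced between the groups.

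Parp1, the targeted gene (ENSMUSG00000026496, chromosome 1, 180568924 to 180601254 in mm10), was slightly lower in the cKO forebrains. Its level was 79.8 ± 0.843 CPM in cKO and 91.2 ± 5.84 CPM in controls (SD, n = 3 mice each). The log2 fold change was -0.19, with a 95% confidence interval from -0.33 to -0.05, and the values of the 3 cKO mice all lay below those of the 3 controls. This did not pass edgeR's quasi-likelihood test after adjustment (adjusted p = 0.572), and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 mice can give. The count covers all exons of the gene and all cells of the forebrain, so it does not measure the deletion within the oligodendrocyte lineage. Parp2, the closest relative of Parp1, was at 23.4 ± 1.58 CPM in cKO and 22.4 ± 1.47 CPM in controls (log2 fold change 0.06, adjusted p = 0.941 by edgeR).

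Across the transcriptome, 45 genes were called between the cKO and control forebrains, and 21 of them, all lower in cKO, were genes of the oligodendrocyte lists. Of 16938 genes tested, 35 fell and 10 rose in cKO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 4 oligodendrocyte lists together held 85 tested genes, and 14 of the genes that fell lay outside them. A gene outside those lists may still belong to the lineage, which was not tested. Of the 35 genes that fell, 21 fell at least 2-fold. Of the 10 that rose, 7 rose at least 2-fold and none was in those lists. At an unadjusted p under 0.05 there were 1062 of the 16938 genes, 596 higher and 466 lower. By chance alone, a share of 0.05 of all tested genes would pass. All 45 called genes had groups that did not overlap, as did 11.9% of all tested genes, where chance gives 10%. When each library was left out in turn, 21 of the lower and 2 of the higher genes were called every time. The number of higher genes was 4 without control replicate 1, 16 without control replicate 3, 6, 5 and 19 without cKO replicates 1, 2 and 3.

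**Figure D1:**
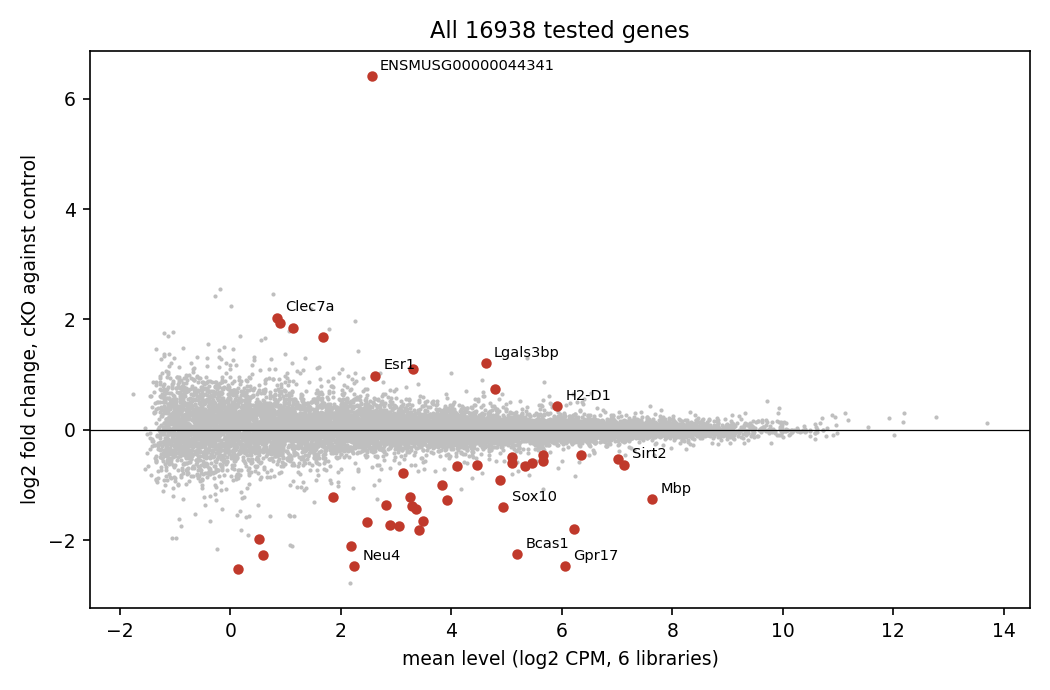
Each point is 1 of the 16938 tested genes, with its mean level over the 6 libraries on the x axis (log2 CPM) and its log2 fold change of cKO against control on the y axis; red points are the 45 called genes. The called genes lie mostly below 0, with 35 lower and 10 higher.

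Genes of newly formed and premyelinating oligodendrocytes fell, with the lowest median log2 fold change of the 4 oligodendrocyte lists. Bcas1, a marker of cells starting to myelinate (chromosome 2, 170346991 to 170427845), fell from 60.7 ± 4.18 to 12.7 ± 1.41 CPM (SD, n = 3 mice each), a log2 fold change of -2.25 (edgeR adjusted p = 9.51e-08). Gpr17, a receptor transiently expressed by committed precursors (chromosome 18, 31942997 to 31949636), fell from 112 ± 19.2 to 20.2 ± 4.02 CPM. Enpp6, a choline phosphodiesterase of newly formed oligodendrocytes, fell by 2.1 on the log2 scale, and Sirt2, a deacetylase of the lineage, by 0.63. Of 19 tested list members, 7 fell, and 13 fell when adjusted over the list alone; 12 did not pass over all genes. The list fell by camera (median log2 fold change -0.63, adjusted p = 7.52e-27), and this held at adjusted p = 0.0149 with an estimated correlation. Exons of Gpr17 overlap those of Lims2 on the opposite strand by 188 bp, and exons of Bcas1 and Sirt2 also overlap genes on the opposite strand, so these counts are less certain. Gpr17 did not pass without cKO replicate 1 (edgeR adjusted p = 0.0655).

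Genes of myelin and mature oligodendrocytes fell as well. Mbp, which encodes myelin basic protein, fell from 281 ± 43.1 to 117 ± 5.94 CPM (SD, n = 3 mice each; fold 2.39, edgeR adjusted p = 2.23e-04). Myrf, the transcription factor that drives myelin gene expression, fell from 17.1 ± 2.48 to 5.38 ± 0.332 CPM, and Ugt8a, which makes the myelin lipid galactosylceramide, fell from 15.1 ± 2.29 to 5.54 ± 0.498 CPM. Gjc3, a glial connexin, fell by 1.75 and Mag, a myelin-axon adhesion protein, by 1.22 on the log2 scale. Other genes of the mature list were not called. Mog, a late myelin glycoprotein, had a log2 fold change of -0.00 (adjusted p = 0.998), and Fa2h, a fatty acid hydroxylase, one of -2.1 (adjusted p = 0.0678). Of 29 tested members 7 fell, Cnp among them with the largest adjusted p of these (0.0452), and 13 fell when adjusted over the list alone. The list passed camera (median -0.32, adjusted p = 4.85e-15), though not with an estimated correlation (adjusted p = 0.168). Mag lost its call without control replicate 1 (edgeR adjusted p = 0.1) and without cKO replicate 1 or 2 (0.0946 and 0.119). Cnp lost it without any single library other than control replicate 2 (0.0889 to 0.191).

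**Figure D2:**
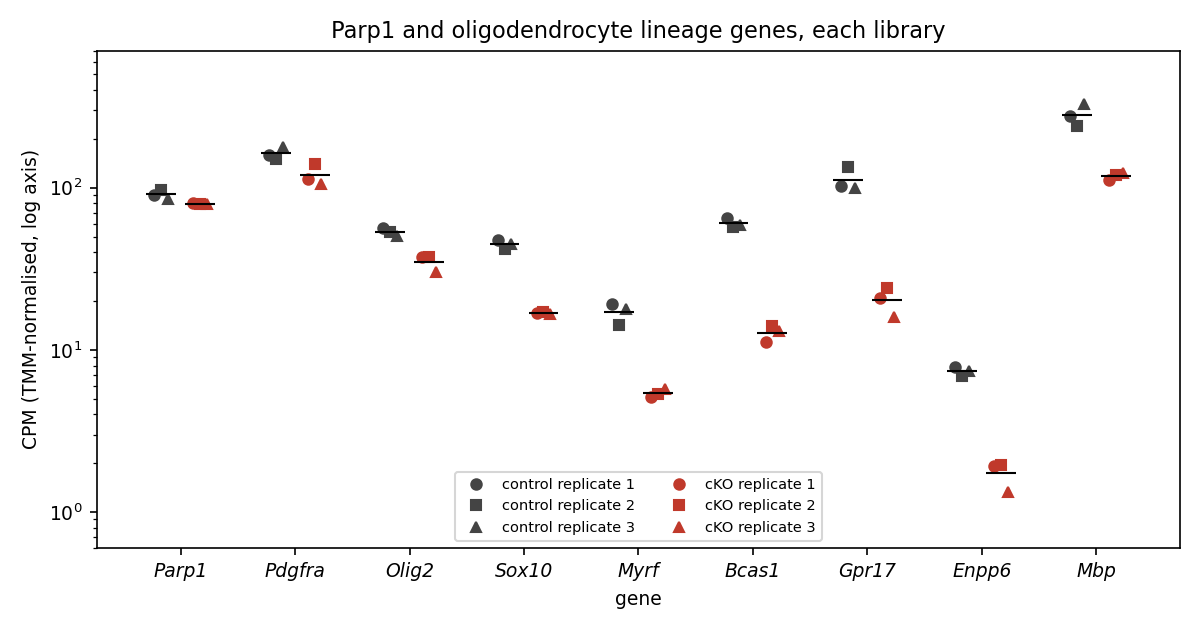
Level of Parp1 and 8 oligodendrocyte lineage genes in each library, in TMM-normalised CPM on a log axis; grey symbols are controls, red symbols cKO, symbol shapes mark replicates and black lines the group means. Mean levels of Bcas1 were 60.7 CPM in controls and 12.7 CPM in cKO, and those of Parp1 were 91.2 and 79.8 CPM.

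Oligodendrocyte precursor genes and lineage transcription factors were also lower, with large differences in size between genes. Among precursor genes, the sialidase gene Neu4 fell from 8 ± 1.57 to 1.42 ± 0.506 CPM (SD, n = 3 mice each; edgeR adjusted p = 4.45e-04), and C1ql1, a secreted C1q-like protein, fell by 1.72 on the log2 scale. Tnr, the matrix protein tenascin-R, fell by 0.57, and Sapcd2 fell by 0.78. Pdgfra, the receptor whose promoter drove the recombinase, was at 119 ± 17.7 CPM in cKO against 163 ± 14.9 CPM in controls, a log2 fold change of -0.45 that was not called (edgeR adjusted p = 0.253). Cspg4, the NG2 proteoglycan, had -0.81 (adjusted p = 0.118). Of 19 tested precursor genes 4 fell, and 13 fell when adjusted over the list alone. The list fell by camera (median -0.24, adjusted p = 2.60e-19), also with an estimated correlation (adjusted p = 0.0257). Exons of Tnr and Pdgfra overlap genes on the opposite strand, so their counts are less certain. Sapcd2 lost its call without any single library other than control replicate 3 (edgeR adjusted p from 0.0563 to 0.185).

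Of the lineage transcription factors, Sox10, which is needed for terminal differentiation, fell from 44.7 ± 2.98 to 16.8 ± 0.301 CPM (SD, n = 3 mice each; edgeR adjusted p = 3.06e-06). Zfp488, a co-regulator of Olig2, fell by 1.67, and Olig2, which specifies the lineage, by 0.61 on the log2 scale. Sox8, a relative of Sox10, had a log2 fold change of -0.63 and just missed the threshold (adjusted p = 0.0501); its exons overlap an antisense gene. Of 18 tested factors 3 fell, and 6 fell when adjusted over the list alone. The list passed camera (median -0.15, adjusted p = 4.55e-07) but had adjusted p = 0.149 with an estimated correlation. Its median was -0.29 without control replicate 2 and -0.09 without control replicate 3, and camera called it both times. Tcf7l2, a factor of both oligodendrocytes and thalamic neurons, was at 144 CPM in control replicate 3 against 28.9 to 36.1 CPM in the other libraries, and was not called. Olig2 did not pass without control replicate 1 (edgeR adjusted p = 0.0846).

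The genes that rose in cKO included Ifi27, the 1 called member of the interferon list, and 6 genes that are in none of the lists: Ifi204, Ifi27l2a, Trim30a, Lgals3bp, H2-K1 and H2-D1. Ifi27, an interferon-induced mitochondrial protein, rose from 6.3 ± 1.02 to 13.5 ± 1.86 CPM (SD, n = 3 mice each; edgeR adjusted p = 0.00619). Ifi204, Ifi27l2a and Trim30a, all interferon-inducible, rose with log2 fold changes of 1.94, 1.83 and 1.68 from levels of at most 1.5 CPM in controls. Lgals3bp, a secreted galectin-binding glycoprotein, rose from 14.9 ± 0.885 to 34.3 ± 4.80 CPM. The class I histocompatibility genes H2-K1 and H2-D1 rose with log2 fold changes of 0.74 and 0.43. The Ifi27 and class I families hold similar copies that may share reads, which was not tested, so their values are uncertain. All 20 genes of the interferon list had a positive log2 fold change, though Ifi27 alone was called, and 17 passed when adjusted over the list alone. Ifit1 was at 2.46 and Rsad2 at 1.62, from low control levels of 0.508 and 0.712 CPM. The list rose by camera (median 1.24, adjusted p = 7.85e-21), which was not kept with an estimated correlation (adjusted p = 0.246). With a mean FPKM of at least 0.5, its median was 0.69 on log2(FPKM + 1) and 0.99 on log2(FPKM + 0.1), over 17 tested genes. Its mean log2 level relative to all libraries was 1.24, 0.41 and 0.16 in cKO replicates 1, 2 and 3, and from -0.73 to -0.53 in controls. Without cKO replicate 1 the calls of Ifi204, Ifi27l2a, Trim30a, H2-K1 and H2-D1 were lost (edgeR adjusted p from 0.0679 to 0.135). Without control replicate 1 those of Ifi27 (0.0563), Ifi204, Ifi27l2a, Trim30a and H2-K1 were lost (0.0673 to 0.116). Ifi204 was also lost without control replicate 2 (0.0563) or cKO replicate 2 (0.0946), Trim30a without control replicate 2 (0.0559), H2-K1 without cKO replicate 2 (0.0795), and H2-D1 without control replicate 2 (0.0701) or cKO replicate 2 or 3 (0.0765 and 0.0721).

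Microglial genes were higher in cKO as a list, and the size depended on control replicate 3. All 20 microglia genes had a positive log2 fold change, among them Fcrls at 0.61 and Csf1r, the receptor microglia need to survive (its exons overlap an antisense gene), at 0.46, but none was called; 10 passed when adjusted over the list alone. The list rose by camera (median 0.47, adjusted p = 2.37e-17), with adjusted p = 0.246 with an estimated correlation. Control replicate 3 had the lowest mean of the list, at -0.56, and without it the median was 0.30 (camera adjusted p = 1.80e-13). Of 19 activated microglia genes 1 rose: Clec7a, the receptor dectin-1, from 0.705 ± 0.301 to 2.88 ± 0.909 CPM (edgeR adjusted p = 0.039), and 2 passed when adjusted over the list alone. That list passed camera (median 0.16, adjusted p = 0.00318; 0.417 with an estimated correlation) but not without control replicate 3 (adjusted p = 0.525). Clec7a lost its call without control replicate 1 or cKO replicate 2 or 3 (edgeR adjusted p = 0.22, 0.258 and 0.15).

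The other 2 genes that rose were Esr1, the estrogen receptor alpha gene, and the identifier ENSMUSG00000044341, which has no name in the annotation used. Esr1 rose from 4.13 ± 0.936 to 8.21 ± 0.577 CPM (SD, n = 3 mice each; edgeR adjusted p = 0.0443). Its call was lost without any single library other than control replicate 3 (adjusted p from 0.0889 to 0.282). ENSMUSG00000044341 had 245 to 317 counts in each cKO library and 2 or 3 in each control. The pooled counts were 855 and 8, a CPM ratio of 88.3 with a 95% interval of 44.6 to 205, which leaves out differences between mice. The edgeR test of 3 mice against 3 gave a log2 fold change of 6.41 (95% confidence interval 5.87 to 6.95, adjusted p = 6.97e-08). ENSMUSG00000044341 was the only gene above 1 CPM in every cKO library and under 0.2 CPM in every control. No gene (0) showed the reverse.

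Genes outside these lists with large falls were Plxnb3, a plexin receptor for semaphorins, Epcam, an epithelial adhesion protein, and 2 genes known only by clone names. Plxnb3 fell from 16.7 ± 1.84 to 4.70 ± 0.310 CPM (SD, n = 3 mice each; edgeR adjusted p = 2.93e-05). Epcam, 1700047M11Rik and A930009A15Rik fell by 2.53, 2.27 and 1.98 on the log2 scale from at most 2.51 CPM. Epcam lost its call without control replicate 1 or 2 or cKO replicate 1 or 3 (edgeR adjusted p from 0.0714 to 0.128), and A930009A15Rik without cKO replicate 2 or 3 (0.0832 and 0.0526).

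The cell cycle, fibroblast, differentiation inhibitor and integrated stress lists passed camera, with no member called over all genes. The cell cycle list rose by camera (median 0.28, adjusted p = 3.47e-07), with Kif11, a mitotic kinesin, at a log2 fold change of 0.77 and Ccnb1, cyclin B1, at 0.61; 1 of 26 genes passed when adjusted over the list alone. With an estimated correlation its adjusted p was 0.365. Without control replicate 3 its median was 0.16 (adjusted p = 0.0056). The fibroblast list rose (median 0.09, adjusted p = 0.0329; 0.654 with an estimated correlation), with Lum at 1.11 and Col6a2, a collagen VI chain, at 0.34, while Pdgfra, which fibroblasts also express, was at -0.45. When adjusted over the list alone, 2 of its 20 genes were higher and 1 was lower. It lost its call without control replicate 1 or 2 (0.287 and 0.173) and without cKO replicate 1 or 2 (0.143 and 0.785). Its median was -0.01 without control replicate 1, -0.02 and 0.04 without cKO replicates 2 and 1, and 0.23 and 0.35 without control replicate 3 and cKO replicate 3. Inhibitors of oligodendrocyte differentiation fell (median -0.08, adjusted p = 0.0329; 0.246 with an estimated correlation), with the transcription factor Sox4, whose exons overlap an antisense gene, at -0.26 and the endothelin receptor Ednrb at -0.27, while Egr1 and Tlr2 were at 0.49 and 0.60. That call was lost without control replicate 1 or 2 (0.122 and 0.0656) and without cKO replicate 3 (0.0904). The integrated stress list fell (median -0.06, adjusted p = 0.0201; 0.246 with an estimated correlation), with the serine synthesis genes Phgdh at -0.23 and Psat1 at -0.21. Its median was -0.10 without control replicate 1. Without control replicate 2 its adjusted p was 0.146 and without cKO replicate 3 it was 0.0904.

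Genes of the PARP family did not pass as a list (adjusted p = 0.114 by camera). The members with the smallest p were Parp14, Parp12, Parp9 and Cgas, with log2 fold changes of 0.93, 0.37, 0.58 and 0.64. None of them was called (edgeR adjusted p from 0.233 to 0.631). Cgas entered the list under its older symbol Mb21d1 and encodes neither a PARP nor an enzyme of ADP-ribose turnover. Parp9, Parp12 and Parp14 are inducible by interferon. Exons of Parp9, Cgas and Myef2 overlap genes on the opposite strand, and those of Parp14 a gene on the same strand. The RNA-binding protein gene Myef2 had a log2 fold change of -0.06 (edgeR adjusted p = 0.922), and the list of RNA-binding regulators had adjusted p = 0.345 by camera, or 0.0135 and lower in cKO without control replicate 3. Camera called none of the lists for cholesterol synthesis (adjusted p = 0.0615), sphingolipid synthesis (0.471), base excision repair (0.861), NAD metabolism (0.901), the p53 response (0.0544) and immediate early genes (0.164). Without control replicate 1 or cKO replicate 1, the cholesterol list passed (3.81e-04 and 3.83e-09). The p53 list passed without control replicate 2 or cKO replicate 1 (0.0361 and 0.0443). Nor were the lists of astrocytes (0.649), neurons (0.267), endothelium (0.344), pericytes (0.1), choroid plexus (0.36) and blood (0.0665) called. Blood passed without control replicate 3 or cKO replicate 1 (3.34e-05 and 0.00224), and endothelium and pericytes without cKO replicate 3 (8.93e-05 and 1.07e-04). The neuron list had a median of 0.05 and a mean of -0.01 and was tested as higher, and the base excision list a median of -0.00 and a mean of 0.05.

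The striatum and thalamus lists depended on control replicate 3. Striatal genes were higher in cKO (median 0.26, camera adjusted p = 1.83e-04; 0.56 with an estimated correlation), and without control replicate 3 they were lower (median -0.13, adjusted p = 0.0438). Without control replicate 1 the median was 0.51. Thalamic genes were lower (median -0.52, adjusted p = 0.0201; 0.622 with an estimated correlation), and without that library the median was 0.03 (adjusted p = 0.289). The thalamus call was also lost without cKO replicate 3 (0.108). No gene of either list was called over all genes or when adjusted over the list alone. Among them, Rgs9, Isl1 and Foxp1 of the striatum had log2 fold changes of 0.20, 0.32 and 0.25, and Tnnt1 and Prkcd of the thalamus -0.72 and 0.25. The hypothalamus list (adjusted p = 0.418) and the olfactory bulb list (0.336; 0.0158 without control replicate 3) were not called, and the midbrain and hindbrain list had 2 tested genes, too few to test. The newly formed oligodendrocyte list did not set control replicate 3 apart in this way. Its mean was 0.44 there, the highest of the 6 libraries, and 0.36 and 0.35 in the other controls.

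**Figure D3:**
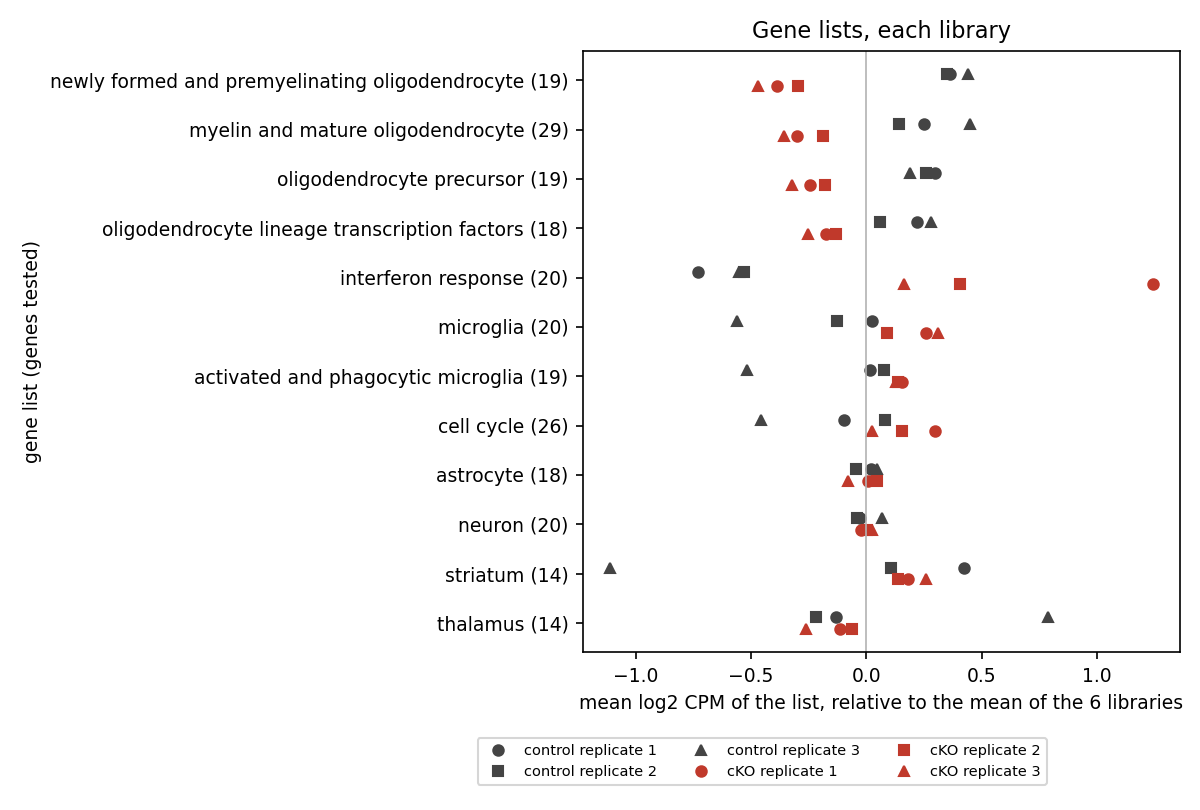
Mean log2 CPM of 12 gene lists in each library, relative to the mean of the 6 libraries; the number of tested genes stands in brackets, grey symbols are controls, red symbols cKO, and symbol shapes mark replicates. The 3 cKO libraries lie from -0.47 to -0.29 for the newly formed oligodendrocyte list, below all controls, and control replicate 3 lies apart at -1.11 for the striatum and 0.79 for the thalamus.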

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

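The covariate for regional make-up (striatum minus thalamus score) was chosen only after control replicate 3 was seen to differ. Parp1 kept its direction and stayed above the threshold in all 22 alternatives. None of the 45 called genes reversed in any. The newly formed and precursor lists passed in every alternative that tests lists. Results that changed side or direction are given here, and the cause was not tested. The number of higher genes was 49 with DESeq2 and 50 with no filter, 17 with limma-voom, 21 with the regional score, 6 without robust dispersion, 4 with Xist as a covariate, 4 on log2(FPKM + 1), 4 on log2(FPKM + 0.1) and 3 on unfiltered FPKM. The number of lower genes was 59 with DESeq2, 61 with no filter, 20 on log2(FPKM + 1), 20 on log2(FPKM + 0.1) and 18 on unfiltered FPKM. Leaving out single libraries gave 4 to 19 higher genes, and 4 to 10 lists that fell. With the replicate number as a block there were 5 higher and 27 lower genes. The numbers share no known origin, and same-number libraries correlated at 0.00425, -0.0461 and 0.00694, so they do not pair the mice.

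Of the named genes that were called, the call was lost in 13 of 22 alternatives for Esr1, in 10 for Epcam, Clec7a, Ifi204 and Sapcd2, in 9 for Trim30a, in 8 for H2-D1, in 7 for H2-K1, in 5 for Olig2 and Ifi27l2a, in 3 for Ifi27, Zfp488, 1700047M11Rik and A930009A15Rik, in 2 for Gpr17 and in 1 for Neu4 and Tnr. Genes not called passed in 8 for Sox8, 4 for Ifit1, 3 for Csf1r, Ifih1, Spp1 and Bgn, 2 for Fcrls, Kif11, Parp14, Pdgfra and Rsad2, and 1 for Laptm5. Lists not called passed as follows. Blood had 0.0359 with no filter, 7.16e-04 with limma-voom, 1.47e-05 with the replicate block and 1.24e-05 with the regional score. Cholesterol had 0.0431 with no filter and 4.34e-04 with Xist, and endothelium 0.00978 with limma-voom. The p53 list had 0.0487 with library size alone, 0.0449 with no filter, 0.0469 with a mean of at least 1 CPM and 0.0405 on unfiltered FPKM. Pericytes had 0.0372 with limma-voom, 0.0494 on log2(FPKM + 1), 0.0491 on log2(FPKM + 0.1) and 0.0224 with the block, and RNA-binding regulators 0.0354 with the regional score. Passes without single libraries are given with these lists' results.

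With an estimated correlation the adjusted p was 0.168 for myelin, 0.149 for transcription factors, 0.246 for inhibitors, microglia, interferon and integrated stress, 0.417 for activated microglia, 0.654 for fibroblasts, 0.365 for the cell cycle, 0.56 for the striatum and 0.622 for the thalamus. With fry it was 0.163 for inhibitors, 0.202 for microglia, 0.562 for activated microglia, 0.749 for fibroblasts, striatum and thalamus, 0.326 for the cell cycle, 0.192 for interferon and 0.218 for integrated stress. Inhibitors had 0.119 with Xist, 0.084 with limma-voom and 0.0582 with the regional score. Fibroblasts had 0.285 with Xist and 0.0966 without X and Y genes. Activated microglia had 0.103 with limma-voom and 0.231 with the regional score. The striatum had 0.137 with limma-voom, and the thalamus 0.907 with limma-voom, 0.0508 on log2(FPKM + 1), 0.075 on log2(FPKM + 0.1) and 0.0515 on unfiltered FPKM. Directions reversed with the regional score for the striatum (0.455), thalamus (0.711), astrocytes (0.863), base excision repair (0.403), hypothalamus (0.361) and Rgs9 (log2 fold change -0.013). They reversed with limma-voom for astrocytes and base excision repair (both 0.486), choroid plexus (0.994), hypothalamus (0.907) and Parp2 (log2 fold change -0.019), on unfiltered FPKM for base excision repair (0.839) and NAD metabolism (0.991), and with Xist for NAD metabolism (0.972).

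Leaving out each library in turn, adjusted p ranged from 2.09e-04 to 0.525 for activated microglia, 1.74e-10 to 0.785 for fibroblasts, 0.0116 to 0.122 for inhibitors, 0.00428 to 0.146 for integrated stress, 9.65e-11 to 0.0438 for the striatum and 1.19e-04 to 0.289 for the thalamus. Of lists with a reversal among these, NAD metabolism ranged from 0.372 to 0.976, astrocytes 0.211 to 0.914, base excision repair 0.353 to 0.849, cholesterol 3.83e-09 to 0.741, endothelium 8.93e-05 to 0.494, hypothalamus 0.106 to 0.846 and sphingolipids 0.129 to 0.709. The log2 fold change of Rgs9 ranged from -0.062 without control replicate 3 to 0.35 without control replicate 1.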

Other observations

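The tests on control replicate 3, cKO replicate 1, the microglia share, the equal loss of stages and the CreER transgene were chosen only after the results they bear on were seen. The class I list was chosen after H2-K1 and H2-D1 were seen to rise, and its bounds were set before the values of its other genes were seen. The bounds for gene length with GC content and for the splits of the libraries were set before those tests were run.

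Outside the oligodendrocyte lists, 14 further genes fell in cKO. The lists do not hold every gene of the lineage, so these may still belong to it. The examples were picked after their values were seen, and no shared function was tested. Pllp, which encodes the membrane protein plasmolipin, fell from 21.4 ± 2.20 to 8.87 ± 0.481 CPM (SD, n = 3 mice each; edgeR adjusted p = 2.02e-04). Kank1, a regulator of the actin skeleton, fell from 38.5 ± 1.99 to 20.4 ± 1.49 CPM, and Prkcq, a protein kinase C, from 14.1 ± 1.17 to 5.45 ± 0.912 CPM. The calcium-binding protein genes S100a13 and S100a1, the adhesion gene Tns3 and the glycolipid transfer gene Gltp also fell. The calls of S100a1, Tns3 and Gltp were lost without 5, 3 and 4 of the 6 libraries in turn, with edgeR adjusted p of up to 0.112, 0.209 and 0.151.

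H2-K1 and H2-D1 were among the genes that rose, and a hypothesis was that class I antigen presentation genes rise as a group in cKO. Of 16 other genes of this pathway 9 had a positive log2 fold change and 0 were called by edgeR, with a median of 0.17. Camera gave p = 0.00275, or p = 0.0326 with an estimated correlation. The members with the smallest p by edgeR were Tap1 and B2m. B2m, the light chain of class I molecules, was at 89.8 ± 7.84 CPM in cKO and 57 ± 12 CPM in controls. The peptide transporter gene Tap1 was at 5.63 ± 0.594 and 3.40 ± 0.372 CPM (SD, n = 3 mice each). Other members had a negative log2 fold change, among them Tap2 at -0.10 (edgeR adjusted p = 0.952). The median lay between the bounds set for a rise of the group (above 0.2) and for none (below 0.1), and without control replicate 3, the library that stood apart, it was 0.21, just above the bound for a rise. Without cKO replicate 1 it was 0.16, and other libraries were not left out for this list. The hypothesis stays open.

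For the lower genes of the newly formed list, a different regional make-up of control replicate 3 is argued against as the whole cause. The median of that list was -0.46 without this library. The other oligodendrocyte lists were not weighed in this way. The mean of the myelin list was 0.45 in control replicate 3, and 0.25 and 0.14 in control replicates 1 and 2. A trend with gene length, GC content or expression is argued against too for the newly formed list. After regression on all of them, which explained 1.18% of the variance, the median of that list was -0.63. An equal loss of every stage of the lineage stays open: the median of the newly formed list minus that of the precursor list was -0.39, with a permutation p of 0.0874 across genes, which are not independent replicates, and it was -0.17 without control replicate 3, -0.25 without cKO replicate 3, -0.16 with limma-voom and -0.20 with the regional score. The same difference per library, on list means relative to all libraries, was -0.136 ± 0.0176 in cKO and 0.136 ± 0.0984 in controls (SD, n = 3 mice each), with no test run on it. A biological effect of the deletion on the lineage may account for the pattern, as a hypothesis, and neither cell loss nor arrested differentiation was tested. It cannot be told apart from an effect of the recombinase itself, which only cKO mice carry.

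The interferon genes were higher in cKO in all 3 libraries, most of all in cKO replicate 1. Control replicate 3 is argued against as the source, since its list mean of -0.55 lay between those of the other controls. Without it the median of the list was 1.29. As the whole source, cKO replicate 1 is argued against, since without it the median was 0.85. Both other cKO libraries also lay above all 3 controls. A larger share of microglia alone is argued against, since without control replicate 3 the microglia median lay apart from the interferon median by -0.99. An effect of the deletion may account for the rest, but it cannot be told apart from an effect of the recombinase, which only cKO mice carry. An infection, litter or cage difference between the mice was not tested, and the list was not called with an estimated correlation. Control replicate 1, the only library with Y-linked expression, had the lowest list mean, at -0.73, and a sex difference was not weighed. With Xist as a covariate the median was 1.15, the list passed camera, and 0 members were called.

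Esr1 and ENSMUSG00000044341 rose in mice that carry a transgene with an estrogen receptor part, and a hypothesis was that reads of the CreER transgene reach these features. Regional make-up of control replicate 3 is argued against for Esr1, since its level there was the highest of the controls, at 5.20 CPM. Leaving that library out could therefore only raise the log2 fold change of Esr1, which was then 1.18. The lowest cKO level of Esr1 was 1.45 times its highest control level, and that of ENSMUSG00000044341 was 63.6 times. Such values may come from the transgene, from regulation of the genes themselves or from other differences between the groups. These cannot be told apart, because only cKO mice carry the transgene. A count per gene also does not show which part of the gene the reads cover. Whether ENSMUSG00000044341 shares sequence with the transgene was not checked.

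For the 45 called genes, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many, the real one, and the highest count among the others was 3. With 10 splits no share under 0.05 can be reached.

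Control replicate 3 had been weighed as a pattern of its own. A first test of RNA quality left the question open, since its mitochondrial share of 2.40% and its ribosomal protein share of 1.77% were the lowest of the 6 libraries. That test was replaced after its result was seen, and the library is now described by its values alone. Slc6a3, the dopamine transporter gene, was at 20.6 CPM there and at 1.01 to 1.56 CPM in the other libraries.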
